A study of Mus musculus with 6 samples.

How the data were processed

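The series describes RNA sequencing of osteoclasts, the multinucleated bone-resorbing cells of the myeloid lineage, grown from wild-type C57BL/6 mouse cells with RANKL and M-CSF, the pair of cytokines that drives osteoclast differentiation. Its 6 samples are 3 controls and 3 cultures given interferon-gamma during differentiation, all labelled day 3. Poly(A) RNA was captured on beads and fragmented before complementary DNA synthesis, and libraries were made with a commercial Illumina kit, per the labels' protocols. The submitters' processing notes name Bowtie2 2.4.4 and the builds GRCm39 and GRCh37, without saying what each was used for; the quantification tool is not given in the sources used here.

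The authors' deposited table holds 570 rows and 6 columns of values. Its name calls it a final list of differentially expressed genes, and the rule by which genes entered it is not given in the sources used here. The values are a deposited normalised expression signal that is never negative; neither the table nor the labels name the unit, so whether they are FPKM or TPM is open. The sums below therefore run over the listed genes and are not library depths. Sequencing depth is unknown. A search for whole-read steps among the low values placed between 18.0% and 24.0% of them within 0.1 step of a whole multiple. FPKM and TPM are divided by transcript length, so in either unit genes would share no step and the search could not find one. Read counts were not recovered and no count model was used.

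Columns were assigned to samples by name alone. Columns named CTRL1, CTRL2 and CTRL3 match the titles of the 3 control samples. The labels give those libraries other names (BLANK1 to BLANK3), so the match rests on the titles. The other 3 columns carry the name FKD with a number, which matches no sample label of the series, and they were not used in any step. As a result 0 columns belong to the interferon-gamma group. The planned test of interferon-gamma against control, its paired form and the tests of gene lists between groups were not run, and no p-value is given.

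For each row the mean and SD over the 3 control columns were computed (n = 3). Nothing in the labels says whether these came from separate animals or cultures, so the SD may be technical. Columns were compared across genes by Pearson's correlation of log2(value + 1) and by Spearman's rho; genes are not independent replicates. Of the 525 rows with a gene symbol, 518 matched a mouse gene name table exactly, 5 matched as an older symbol or synonym, and 2 did not match. The other 45 rows have the MSTRG prefix of transcripts assembled from reads and carry no gene name. The supplied annotation is of GRCm38, another build than the one in the processing notes, so no coordinates are printed.

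Before the data were examined, 29 gene lists (524 different symbols) were fixed for interferon responses, osteoclast biology, metabolism and the markers of other cells. List sizes count symbols: Tm7sf4 is an older symbol of Dcstamp and Ddx58 of Rigi, and each was counted separately. A rule for named genes was fixed too. It ranked genes by their change between groups, which could not be computed, and added 8 genes of osteoclast differentiation and interferon signalling in any case, of which 0 are among the rows. The genes named below were therefore chosen after their values were seen: the 5 highest rows, and members of the lists picked from among those in the table; the closing observations add a few genes on none of the lists. A further 4 lists, for squamous epithelium, hair or papilla keratins, skeletal muscle and secretory glands, were written after the values were seen. For a list with at least 3 members in the table, the median of the members' means was placed among the medians of 10000 random lists of the same size drawn from the 570 rows, as a description of these libraries. In a simulation of 570 rows, 40 of 40 lists of 20 genes raised 8-fold passed the 95th percentile of random lists, as did 3 of 40 unchanged lists. The simulated lists were drawn at random, so these rates do not apply to the 4 lists written after the values were seen. The fixed lists given a percentile had only 3 or 4 members in the table, a size that was not simulated. Alternatives were other pseudocounts (0.1 and 5), filters on low values (a mean of at least 1 or 5) and leaving out each control column in turn. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.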

Results

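The series was designed to ask how interferon-gamma changes the transcriptome of osteoclasts induced with RANKL and M-CSF. Expression values could be assigned to the 3 control samples only. None of the table's other columns matched a label of the 3 interferon-gamma samples, so the comparison between the groups was not made and no gene is reported as changed. What follows describes the 3 columns labelled control. Of the 29 rows with a mean of at least 100 in these columns, 17 are on a list of genes known from squamous epithelium, 3 on a skeletal muscle list, 1 on a secretory gland list, 1 on a chemokine list and 7 on no list. The epithelium, muscle and gland lists were written after the values were seen, so these counts partly reflect that choice. The chemokine list was fixed before. The assignment of the columns to osteoclast cultures rests on the column names alone.

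The table lists 570 rows that its name presents as differentially expressed genes, so a gene outside it cannot be read as unexpressed. Over these rows the values summed to 13620 in control 1, 13318 in control 2 and 13508 in control 3, with medians of 1.22, 1.16 and 1.21. A mean of at least 1 was reached by 306 rows, of at least 10 by 85 rows and of at least 100 by 29 rows. The 10 highest rows held 56.7% of the summed values. An exact 0 stood in at least 1 of the 3 columns for 5 rows, among them Camp, which was listed at 0 in control 1, 0.298 in control 2 and 0.547 in control 3.

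Over the listed rows, the 3 control columns were close to one another. Pearson's r of log2(value + 1) across the 570 rows was 0.9961 between controls 1 and 2, 0.9958 between controls 1 and 3 and 0.9963 between controls 2 and 3, with Spearman's rho of 0.980 for each of these. At most 1 row had an identical value in any 2 columns, so no column was a copy of another. The median coefficient of variation was 7.63% for rows with a mean of at least 1 and 21.7% for rows below 1. The rows were selected by an unknown rule that may favour genes of small spread, and their levels differ widely. These figures therefore describe the listed rows and not the reproducibility of whole libraries.

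Genes of the cornified envelope, the protein shell of differentiated keratinocytes, and of other keratinocyte proteins made up 6 of the 10 highest rows. The row with the highest mean was Mt4, a metallothionein known from stratified squamous epithelium, at 2087 ± 203 (SD, n = 3), with control 1 at 2321 and the other columns at 1960 and 1981. The next 4 rows were on no list: the predicted gene Gm94 at 1899.8 ± 48.9, Ide, the insulin-degrading enzyme, at 785 ± 32.5, Nupr1, a stress-responsive nuclear protein, at 503 ± 9.38 and Fmo2, a flavin-containing monooxygenase, at 475 ± 18.8 (SD, n = 3). Below them came late cornified envelope genes: Lce1a1 stood at 430.3 ± 5.32, Lce1d at 386 ± 7.31, Lce1a2 at 379 ± 3.13 and Lce1b at 363 ± 10.6 (SD, n = 3). Kprp, a keratinocyte proline-rich protein, had a mean of 227 ± 5.99, and Sprr2d, a small proline-rich envelope precursor, 229 ± 7.05. Flg, which encodes the keratin-aggregating protein filaggrin, was lower, at 16.4 ± 0.323. Of 49 genes on the list for cornified envelope and keratinocytes, 26 were in the table, and 21 of these had a mean of at least 10. Mt4 alone held 15.5% of the summed values, and all 26 together held 46.6%. Their median of 195 ± 7.24 (SD of the library medians, n = 3) lay above the median of every one of 10000 random lists of the same size from the table. The Lce1 and Sprr2 genes are families of similar sequence, so the share of reads given to each member is uncertain. The list was written after the values were seen.

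Genes of the contractile apparatus and energy supply of skeletal muscle held the next largest share of the summed values among the lists. Acta1, the skeletal muscle actin, had a mean of 186 ± 6.45, Mylpf, a fast-fibre myosin light chain, 153 ± 3.97, and Mb, the oxygen carrier myoglobin, 150.2 ± 3.17 (SD, n = 3). Myl1 stood at 87.4 ± 5.94, the muscle creatine kinase Ckm at 56.3 ± 0.876, the muscle enolase Eno3 at 34.6 ± 1.13 and the myosin heavy chain Myh1 at 20.9 ± 0.521. The giant sarcomere protein gene Ttn was at 0.227 ± 0.00148. Of 62 genes on the muscle list, 47 were in the table and 16 had a mean of at least 10. The list's median was 2.45 ± 0.184, at percentile 99.0 of random lists, and it held 6.70% of the summed values. Over the members with a mean of at least 1 the median was 10.5. This list too was written after the values were seen, and it does not hold every muscle gene of the table. Myom3 (0.615), Mybph (0.307) and Scn4a (0.130) are off it, as are Csrp3 (10.8) and Tmod4 (6.07). Its median and percentile therefore depend on the members chosen.

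Secreted proteins of glands and odorant-binding lipocalins held 2.81% of the summed values. Crisp1, a cysteine-rich secretory protein, had a mean of 249 ± 18.0 (SD, n = 3) and made up 65.8% of the list's sum; the other 19 members in the table held 0.962% of the summed values. Smgc, a submandibular gland protein, was at 24.5 ± 5.60, with control columns at 25.7, 18.4 and 29.4. Bpifb9b was at 23.8 ± 1.35, and the odorant-binding protein genes Obp1a and Obp1b were at 14.8 ± 1.26 and 12.5 ± 1.32. Of 33 genes on this list 20 were in the table, with a median of 5.58 ± 0.448. Among hair and filiform papilla keratins, 6 of 16 listed genes were in the table, led by Krt32 at 33.0 ± 1.92, and the keratin-associated protein gene Krtap13 stood at 6.87 ± 1.25. The medians of these lists lay at percentiles 99.9 and 93.8 of random lists. Both lists were written after the values were seen.

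**Figure D1:**
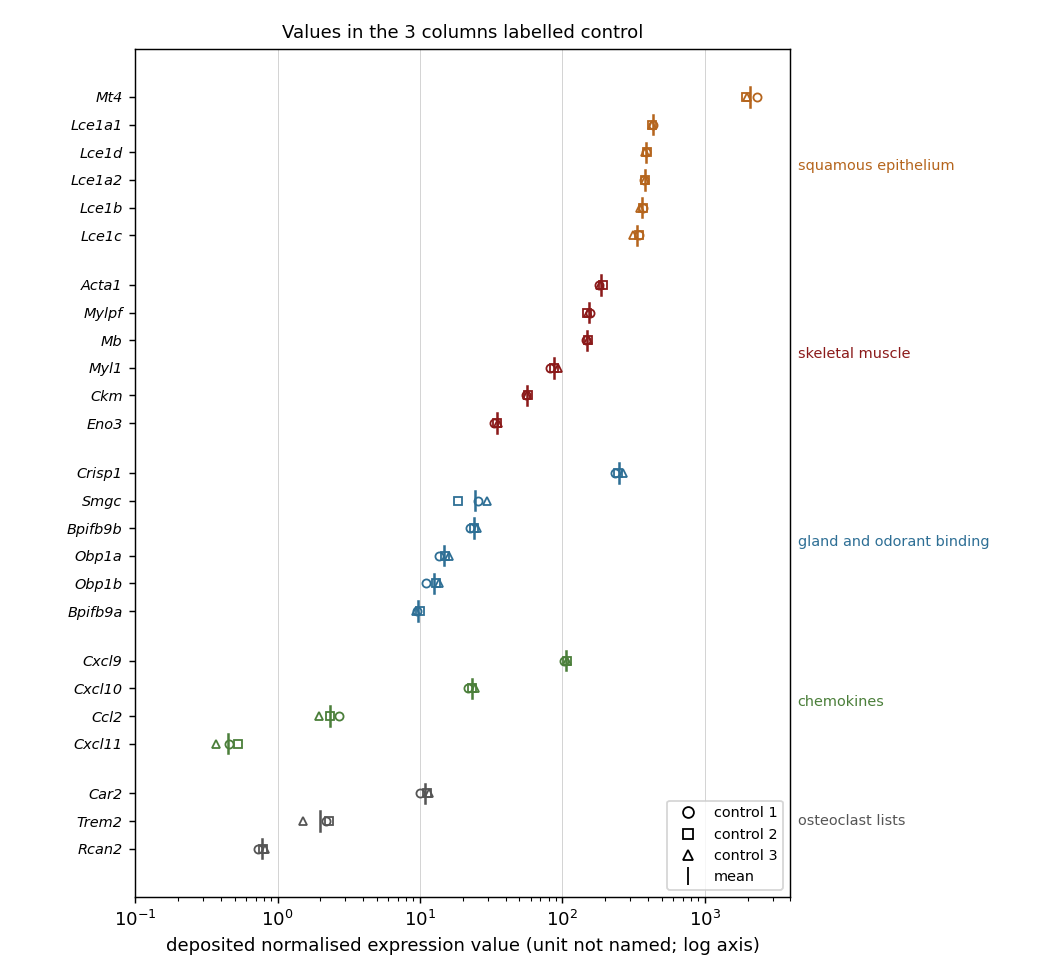
Deposited normalised expression values (horizontal log axis, unit not named) of up to 6 members with the highest means from 5 groups of genes; open symbols are the 3 columns labelled control and vertical bars their means. Mt4, at a mean of 2087, and the plotted Lce1 genes lie to the right of Car2, Trem2 and Rcan2, the members of the osteoclast lists that are in the table. The epithelial, muscle and gland lists were written after the values were seen, and the table holds selected genes. The positions therefore do not show how abundant osteoclast genes were.

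Of the 54 different symbols on the 3 lists fixed for osteoclasts, 3 were among the rows (5.56%), beside 36 of the 524 symbols on all fixed lists (6.87%). Car2, the carbonic anhydrase that supplies protons for resorption, had a mean of 10.9 ± 0.829 (SD, n = 3). Trem2, a myeloid receptor that signals through DAP12, stood at 2.00 ± 0.429, and Rcan2, a calcineurin regulator, at 0.781 ± 0.0435. These are 1 of 20 symbols on the resorption list, 1 of 15 on the fusion list and 1 of 20 on the list of RANK signalling and transcription factors. The lists of V-ATPase subunits, lysosomal proteins, anti-osteoclastogenic regulators, cytoskeleton and podosome genes, mitochondrial respiration and macrophage markers had 0 members in the table.

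Interferon-response genes were present in part. Cxcl9 and Cxcl10, chemokines that interferon-gamma is known to induce, had means of 106.0 ± 2.997 and 23.1 ± 1.23 (SD, n = 3) in the columns labelled control, while Cxcl11, of the same family, was at 0.450 ± 0.0767 and Ccl2 at 2.32 ± 0.365. These are 4 of 25 genes on the list of chemokines and their receptors, and their median lay at percentile 94.98 of random lists. The interferon-inducible GTPase genes Tgtp1, Irgm2 and Gbp10 were at 14.5 ± 0.518, 2.75 ± 0.172 and 0.444 ± 0.0666. They are 3 of 20 genes on the GTPase list, so the list median, at percentile 76.7, is the value of Irgm2. Of the antiviral genes, Ifit1 was at 15.8 ± 0.745, whereas Oas2, Oas3 and Rsad2 all lay below 1, at 0.334 ± 0.131, 0.156 ± 0.0594 and 0.369 ± 0.0872. These are 4 of 30 symbols on the antiviral list, and their median was at percentile 5.37 of random lists. None of the 51 genes on the lists for interferon-gamma signalling and for class I and class II antigen presentation was among the rows analysed here. The same held for the lists of co-stimulation and checkpoint ligands and of cell death genes.

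Of the inflammatory list 3 of 21 genes were in the table, and of the complement list 3 of 14. Tnf and the complement genes lay above the median of the row means (1.18), and Ptgs2 and Acod1 below it. Tnf was at 3.95 ± 0.538, Ptgs2, the inducible cyclooxygenase, at 0.686 ± 0.0111 and Acod1, which makes itaconate, at 0.358 ± 0.0951 (SD, n = 3). C3, the central complement component, was at 5.21 ± 0.358, Cfb at 2.71 ± 0.163 and C4b at 1.26 ± 0.193. The medians of the inflammatory and complement lists, which are the values of Ptgs2 and Cfb, lay at percentiles 34.2 and 76.1 of random lists.

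Markers of other cells were also listed. The secreted iron-binding protein gene Lcn2, used as a neutrophil marker but also made by epithelium, had a mean of 66.7 ± 1.46 (SD, n = 3). The neutrophil granule genes Ngp and Camp were at 0.640 ± 0.187 and 0.282 ± 0.274. These are 3 of 13 genes on the neutrophil list, so its median, at percentile 32.0, is the value of Ngp. Bglap, which encodes the osteoblast product osteocalcin, was at 36.7 ± 2.15 and was the member of the stromal and osteoblast list in the table. Gzma, a lymphocyte protease and the 1 of 17 genes on the lymphocyte list that was in the table, was at 0.606 ± 0.144. From the dendritic cell list, Dpp4 was at 6.35 ± 0.313 and Irf4 at 0.198 ± 0.0144. Genes of the erythroid, mast cell and basophil list were not among the rows.

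The cell cycle genes Top2a, Ccnb1 and Cdk1 had means of 7.34 ± 0.198, 6.00 ± 0.154 and 3.31 ± 0.0181 (SD, n = 3). They are 3 of 20 genes on the cell cycle list, so its median, at percentile 89.2, is the value of Ccnb1. Of genes for lipid handling, the lipase Lpl was at 5.53 ± 0.470 and the fatty acid transporter Cd36 at 4.08 ± 0.681. The hexokinase gene Hk3 was at 0.343 ± 0.0803. The matrix genes Col4a1 and Mmp8 were at 1.02 ± 0.0828 and 0.731 ± 0.195, and the stress-response transcription factor gene Atf3 was at 6.11 ± 0.451.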

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

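No paired analysis was possible because none of the table's columns matched an interferon-gamma sample, so the replicate numbers that the labels give to both groups have values in the control group only; the alternatives planned for the test between groups were not run for the same reason. The lowest correlation between control columns, 0.9958 with a pseudocount of 1, was 0.9900 with 0.1 and 0.9981 with 5. It was 0.9954 on rows with a mean of at least 1 and 0.9972 on rows with a mean of at least 5. Leaving out a column leaves a single pair, so the values from 0.9958 to 0.9963 are the pairwise correlations themselves and test nothing further. The share of the summed values in the 10 highest rows, 56.7%, was 51.0% without Mt4. The number of rows with a mean of at least 1 (306) was 302 by the median of the columns and between 303 and 311 with 1 column left out. For the 11 lists with at least 3 members, leaving out 1 column moved a median by at most 1.16 times. Restricting lists to members with a mean of at least 1 raised 6 of 11 medians by over 1.5 times, since the restriction removes the low members. The muscle median rose from 2.45 to 10.5 and that of chemokines from 12.7 to 23.1. For GTPases it rose from 2.75 to 8.65, with only Tgtp1 and Irgm2 left. Some lists kept a single gene, so their restricted values are not list levels. Antiviral genes kept Ifit1 (0.352 to 15.8), inflammatory genes Tnf (0.686 to 3.95) and neutrophil markers Lcn2 (0.640 to 66.7). Depth is unknown, so the counting error of the low values cannot be given.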

Other observations

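Beyond the genes already described, the columns labelled control held values of single genes that were on none of the lists. Ctla4 had a mean of 1.84 ± 0.165, Cd7 1.27 ± 0.187, Pdcd1 0.443 ± 0.123, Cd247, a T-cell receptor signalling chain, 0.341 ± 0.0981 and Il17a 0.438 ± 0.194 (SD, n = 3). The enamel matrix genes Amelx and Ambn, known from tooth-forming ameloblasts, were listed at 1.03 ± 0.116 and 0.324 ± 0.0506. Csf1, which encodes M-CSF, was at 1.44 ± 0.0731. These genes were picked by hand after their values were seen and were not tested as a group; of the 17 genes on the fixed lymphocyte list, 1 was in the table.

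The values of epithelial and muscle genes stand out in columns that were matched to osteoclast controls by name alone (all tests of this pattern were chosen after it was seen). A single deviating library does not account for them, since the list medians for squamous epithelium and muscle differed by at most 1.15 times between libraries. One hypothesis is that the table was made from another tissue than osteoclast cultures; the higher of the list medians lay at percentile 100 of random lists, but those lists were written after the values were seen, so this percentile cannot settle it. The 3 columns named FKD, which match no label of the series, and the other library names given for the controls leave open that the table belongs to other samples. Of the 51 genes on the lists for interferon-gamma signalling and antigen presentation, 0 are among these rows, which the table's name presents as differentially expressed. The interferon-inducible genes Cxcl9, Cxcl10, Tgtp1 and Ifit1 are among them. Because the selection rule is not given, these memberships do not settle which samples the table came from. Epithelial and muscle cells carried over into the cultures may be the source instead, and this cannot be told apart here. Only 3 of the 71 symbols on the fixed osteoclast and macrophage lists are among the rows (their median was at percentile 67.6). A table of selected genes does not show how abundant the rest were. The design names no biological difference among the 3 control samples, so no biological explanation was tested.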
